A study of Homo sapiens with 6 samples.

How the data were processed

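Total RNA from 6 cultures was measured on an Affymetrix whole-transcript array, with 3 arrays of UCSF4 hESCs and 3 of NPCs derived from them. Per the labels' protocols, RNA was purified on columns, checked by capillary electrophoresis, and amplified and biotin-labelled with a Ribo-SPIA kit. Per the submitters' processing notes, the arrays were processed in Affymetrix Expression Console with RMA. The versions, the genome build and the scan batches are not given in the sources used here. The deposited table holds log2 values made by the authors with RMA, which corrects background, quantile-normalizes the arrays and summarizes each probe set. The deposited values ran from 0.296 to 13.7, and the sorted columns differed by at most 0.136, so the arrays had already been put on nearly 1 distribution. Quantile normalization sets the arrays to a common distribution, so a change shared by most genes would not show. RMA also compresses differences of dim and very bright genes, and the table has no detection calls, so a low value cannot be told from background.

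The table held 53617 probe sets. A platform annotation gave exactly 1 gene symbol for 16098 of them (30.0%) and several for 0. The other 37519 probe sets are unnamed here and entered no named comparison. Symbols were updated through Entrez identifiers to the RefSeq gene table of assembly GRCh38.p14, which matched 16098 of the 16098. That table was used for names, gene types and chromosomes, and no coordinates are given since the authors' build is not known here. A gene with several probe sets was represented by the one with the highest mean over the 6 arrays. There were 14105 genes with 1 probe set and 779 with several, and in 1 gene the called probe sets disagreed in direction. Genes that determine or reveal donor sex are not reported. No further normalization and no filter on dim genes was applied.

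The groups and replicate numbers came from the sample titles. The main test was limma's linear model with empirical Bayes moderation (lmFit and eBayes, limma 3.58.1 in R 4.3.3), NPC minus hESC, two-sided, with Benjamini-Hochberg adjustment over the 14884 genes and a threshold of 0.05. The error after a difference is the moderated standard error, and the error after a group mean is the SD of 3 arrays. The error after the median of a gene set is a bootstrap SE over its genes, not a spread between cultures. There were 19 gene lists, fixed before the data were examined: pluripotency; neural progenitor and neuroectoderm; neuronal; glial; forebrain and eye field; midbrain, hindbrain and spinal cord; neural crest; mesenchymal and fibroblast; mesoderm and endoderm; surface ectoderm and trophoblast; epithelial junction; cell cycle; Notch pathway; FGF and ERK feedback; LIF and STAT3 response; DNA methylation and demethylation; imprinted; glycolysis; and stress response. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 19 lists. Members of a list with no named probe set are not analysed here, and counts are of measured members.

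The genes named in the text were also chosen by a rule set before the data were examined. It took POU5F1, NANOG, SOX2, PAX6, SOX1 and NES whatever their values. It added the 10 highest and 10 lowest differences among called genes whose groups did not overlap, and from each list the 2 called members that moved most in the majority direction and the 1 that moved most the other way. Small noncoding RNAs, uncharacterized or open reading frame symbols, histone and protocadherin clusters and genes that reveal donor sex were left out of the ranked and list-based choices. The rule gave 68 genes, and any other gene is marked in the text as chosen after its value was seen.

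The alternatives tried were the replicate number as a block, a second quantile normalization, centring on the median, eBayes with trend and robust settings, array weights, filters on genes below the 25th or 50th percentile of level, the mean of a gene's probe sets, all probe sets, limma treat, an unmoderated test, camera with an estimated correlation, fry, lists without dim members, and leaving out each array in turn. The restriction to protein-coding genes was added after seeing the data.

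The code was tested on simulated data with the means and spreads of the 14884 genes of this comparison, with 200 genes changed, over 20 runs. It recovered 21.0% of genes changed by 0.5 on the log2 scale, 73.0% of those changed by 1 and 97.7% of those changed by 2. Of the genes called, 4.69% had not been changed. A list of 25 genes raised by 0.5 was called in 100% of the runs. In the real comparison 35.3% of the genes were called, far more than were changed here, so these rates do not carry over to it. The simulated genes varied independently, so the list result does not cover lists with correlated members. Figures were drawn with matplotlib 3.10.9.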

Results

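The series measured gene expression in UCSF4, a human embryonic stem cell (hESC) line, and in neural precursor cells (NPCs) made from it. The 2 groups held 3 arrays each. The hESC RNA came from separate wells of undifferentiated colonies at passage 22, and the NPC RNA from separate wells at passage 5. NPCs were obtained through embryoid bodies and neural rosettes and were then kept in medium with FGF2 at 20 ng/mL and LIF at 10 ng/mL, and both cell types were grown at 8% oxygen. Values are log2 RMA values per gene, so a difference of 1 is a 2-fold change. The arrays carry no read depth, and their number limits the precision. Because the wells of a group share the line and the passage, p-values measure only the spread between these wells.

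Arrays of a group lay close together and the groups lay far apart. Over 14884 genes, Pearson's r between arrays of the same group was 0.991 to 0.993, and between hESC and NPC arrays it was 0.930 to 0.934. These correlations run across genes, which are not independent replicates. The first principal component held 84.7% of the variance and separated the groups. The second held 4.30%, and hESC replicate 3 lay at -20.9 on it, against 11.7 and 9.44 for the other hESC arrays. The median standard deviation within a group was 0.157.

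The comparison of NPCs with hESCs asks which genes differ between pluripotent cells and their neural derivatives. The 10 lowest differences include genes of pluripotent and epithelial cells and of metal binding. ESRG, a long noncoding RNA of embryonic stem cells (probe set 16955167), went from 11.37 ± 0.058 (SD, n = 3) in hESCs to 2.74 ± 0.039 in NPCs, 397-fold lower. L1TD1, an RNA-binding protein of pluripotent cells, fell by 8.60 ± 0.21 (SE), and ZFP42, a zinc finger protein of stem cells also called REX1, fell by 8.12 ± 0.11. The largest rises were in A2M, the protease inhibitor alpha-2-macroglobulin (probe set 16761012), from 3.44 ± 0.31 to 10.74 ± 0.13 or 157-fold, and in HOXA2, a homeobox gene of the hindbrain, by 6.62 ± 0.17 or 98.1-fold. The lower value of each of these genes may be background, so the size of its change is uncertain.

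Out of the 14884 genes, 2662 were higher and 2587 lower in NPCs at an adjusted p under 0.05 in limma, 35.3% of the genes together. With a difference of at least 2-fold as well, 856 were higher and 786 lower. When the 2-fold difference itself was tested (limma treat), 401 were higher and 363 lower. The groups did not overlap in 47.5% of the genes, where chance gives 10% for 3 arrays against 3. The smallest difference called was 0.272, and the other 9635 genes are not shown to be equal.

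The 10 genes with the highest differences have varied known roles. NCALD, the neuronal calcium sensor neurocalcin delta, rose by 6.04 ± 0.16, and DCC, the netrin receptor of growing axons, rose by 5.38 ± 0.17. ASXL3, a chromatin regulator, rose by 5.19, the transcription factors PAX3, EBF1 and DACH1 by 4.84, 4.69 and 4.64, and the secreted matrix proteins MMRN1 and LUM by 5.14 and 4.70. Their adjusted p-values ran from 3.71e-08 to 4.96e-06. Among the 10 lowest, the metallothioneins MT1H and MT1G, which bind zinc and copper, fell by 8.56 ± 0.17 and 7.69 ± 0.14. ESRP1, a splicing regulator of epithelial cells, fell by 7.01 ± 0.11, and EPCAM, an epithelial adhesion molecule, by 6.28 ± 0.13. ARHGEF35, FAR2P2 and D21S2088E fell by 6.58, 6.45 and 6.33. The metallothioneins, ARHGEF35 and FAR2P2 have near-identical copies in the genome that can share probes, so their own values are uncertain.

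**Figure D1:**
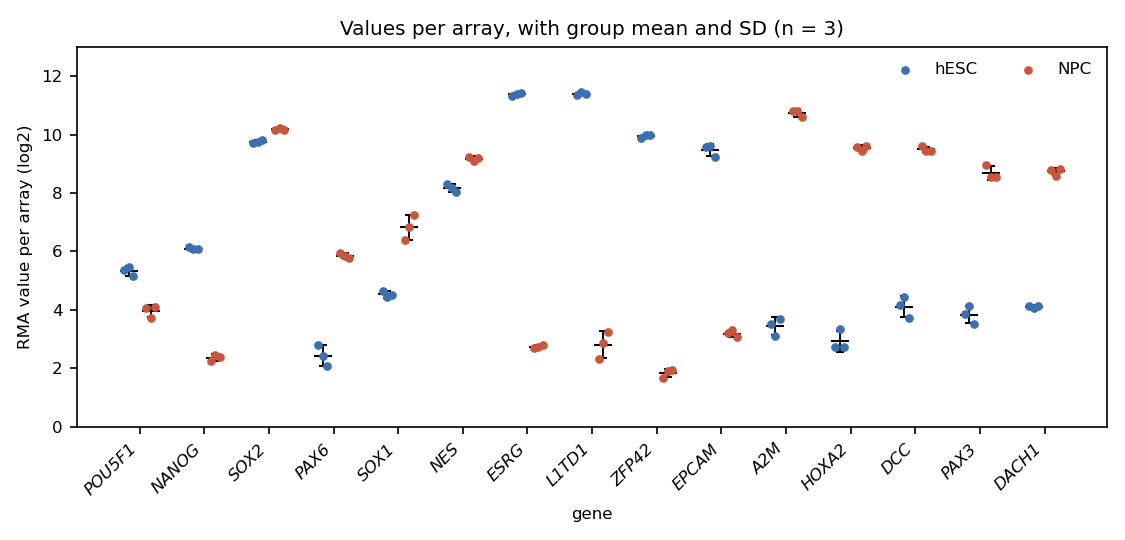
Log2 RMA value on each array (vertical axis) for 15 named genes (horizontal axis), with hESC arrays in blue and NPC arrays in red, 3 points per group, and black bars for the group mean and SD. The groups do not overlap in any of the 15, with ESRG at 11.37 in hESCs and 2.74 in NPCs and HOXA2 at 2.92 and 9.54.

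Genes of the pluripotent state fell together. Of the 28 measured members of the pluripotency list, 24 fell, 0 rose and 4 did not pass (DPPA2, FGF4, UTF1 and KLF4). Adjusted over the list alone the counts were also 24 and 0. The 4 had low hESC means of 2.81, 4.40, 4.85 and 4.29, so they are not shown to be kept in NPCs. The mean difference of the list was -2.87 (camera adjusted p = 1.43e-17, and adjusted p = 0.0102 with an estimated correlation). NANOG, a core transcription factor of pluripotency, fell by 3.73 ± 0.10 (13.3-fold, adjusted p = 1.18e-07). POU5F1, which encodes OCT4, fell by 1.37 ± 0.14, from 5.33 ± 0.16 to 3.96 ± 0.22 (2.59-fold, adjusted p = 0.000127). Its copies elsewhere in the genome can share probes with it, so the level is uncertain. The falls were unequal: the RNA-binding proteins LIN28A and LIN28B fell by 2.54 ± 0.105 and 0.68 ± 0.096, and the transcription factor SALL4 by 0.90 ± 0.11. LIN28A, LIN28B and SALL4 were singled out after their values were seen.

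Neural progenitor genes rose. Of 26 measured members of the neural progenitor and neuroectoderm list, 22 rose, 2 fell and 2 did not pass, with the same counts of 22 and 2 adjusted over the list alone. The mean difference was 1.83 (camera adjusted p = 6.51e-13, and adjusted p = 0.0154 with an estimated correlation). PAX6, a transcription factor of the neural plate, rose by 3.43 ± 0.17 (10.8-fold, adjusted p = 2.29e-06), and SOX1, an early neuroectoderm factor, by 2.29 ± 0.20 (4.90-fold, adjusted p = 5.01e-05). NES, the intermediate filament nestin, rose by 0.99 ± 0.11 (1.99-fold, adjusted p = 0.000213). SOX2, which both pluripotent and neural stem cells use, was already high in hESCs at 9.76 ± 0.065 and rose by 0.42 ± 0.095 (1.34-fold, adjusted p = 0.00915). DACH1 and the homeobox gene MEIS1 rose most, by 4.64 ± 0.105 and 4.52 ± 0.096. POU3F1, a POU-domain factor, fell by 0.94 ± 0.14.

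More neuronal genes rose than fell, and glial genes moved both ways. Of 17 measured neuronal members, 11 rose, 1 fell and 5 did not pass (12 and 1 adjusted over the list alone), with a mean of 1.02. The camera adjusted p was 9.06e-05, with an estimated correlation it was 0.0474, and it was 0.0715 when genes below the 50th percentile of level were left out. MAP2, a microtubule protein of dendrites, rose by 3.41 ± 0.096 (10.6-fold), and STMN2, a tubulin-binding protein of growing axons, by 3.36 ± 0.14 (10.2-fold). SYT1, a synaptic vesicle calcium sensor, fell by 0.56 ± 0.099. Of 17 glial members, 4 rose, 4 fell and 9 did not pass (4 and 5 adjusted over the list alone; camera adjusted p = 0.639). S100B, a calcium-binding protein of astrocytes, rose by 1.69 ± 0.18 and NFIB, a transcription factor of gliogenesis, by 1.00 ± 0.12, while the lipoprotein gene APOE fell by 1.61 ± 0.23. GFAP, the astrocyte filament, differed by -0.24 ± 0.12 and did not pass (adjusted p = 0.164). GFAP was singled out after its value was seen.

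Regional genes mark positions from the front to the back of the neural tube. Of 19 measured members of the midbrain, hindbrain and spinal cord list, 10 rose, 0 fell and 9 did not pass, with the same 10 and 0 adjusted over the list alone. The mean was 1.28 (camera adjusted p = 0.000118, but adjusted p = 0.129 with an estimated correlation). HOXA2 and PAX3, a factor of the dorsal neural tube, rose most (98.1-fold and 28.6-fold). HOXB2, a second hindbrain gene, rose by 4.21 ± 0.28, EN2 of the midbrain and anterior hindbrain by 2.31 ± 0.17, and GBX2 of the anterior hindbrain by 1.28 ± 0.16. HOXB3, HOXB4 and HOXB5 differed by 0.046 ± 0.14, 0.013 ± 0.11 and -0.29 ± 0.18 and did not pass. These 6 genes beside HOXA2 and PAX3 were chosen after their values were seen.

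Of 17 measured forebrain and eye field members, 0 rose, 5 fell and 12 did not pass, also 0 and 5 adjusted over the list alone. The mean was -0.86 and the median -0.12 (camera adjusted p = 0.0326). The call was lost with an estimated correlation (adjusted p = 0.129), without hESC replicate 3 (adjusted p = 0.0526), and with protein-coding genes only, a setting chosen after seeing the data (adjusted p = 0.0502). OTX2, a homeobox gene of the forebrain and midbrain that pluripotent stem cells also express, fell by 5.12 ± 0.11 (34.8-fold) and FEZF1, a zinc finger gene of the forebrain, by 4.37 ± 0.21 (20.7-fold). OTX2 and HESX1, a homeobox gene of the anterior neural plate that fell by 3.66, are also known from undifferentiated pluripotent cells; HESX1 was chosen after its value was seen.

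**Figure D2:**
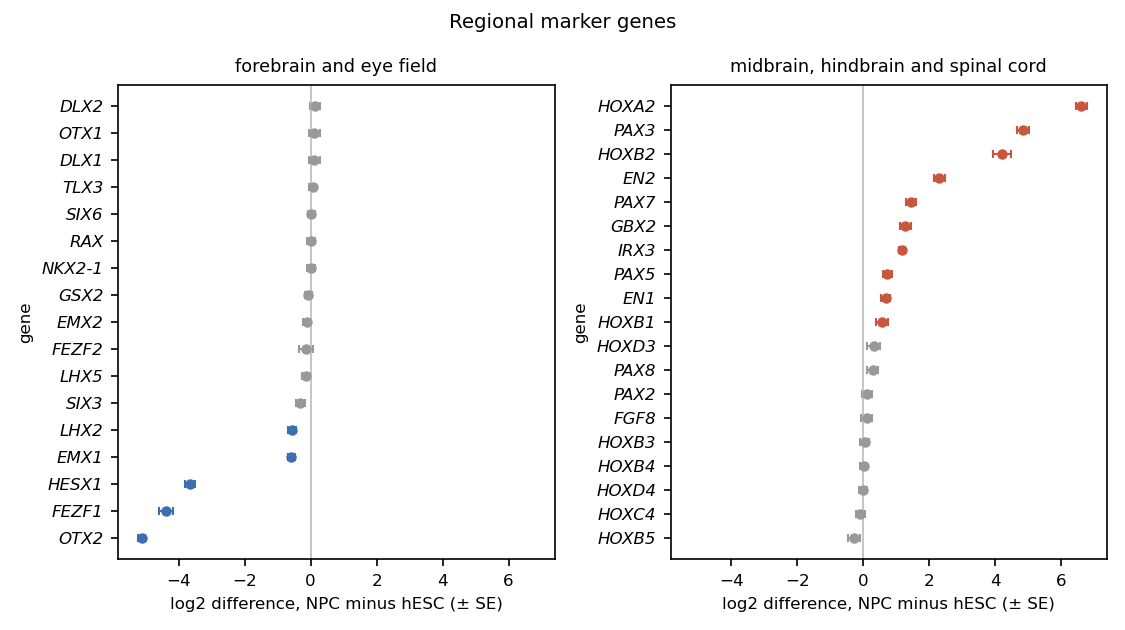
Log2 difference between NPC and hESC means (horizontal axis, points, with SE bars, 3 arrays per group) for each measured gene (vertical axis) of the forebrain and eye field list on the left and the midbrain, hindbrain and spinal cord list on the right. Red and blue mark genes higher and lower in NPCs at an adjusted p under 0.05 and grey marks the rest; HOXA2 lies at 6.62 and OTX2 at -5.12.

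Markers of neighbouring cell types moved in both directions. Of 15 measured neural crest members, 5 rose, 4 fell and 6 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.441). PAX3 and TFAP2B, transcription factors of the neural plate border and crest, rose by 4.84 ± 0.18 and 4.24 ± 0.22, while FOXD3, which is a pluripotency list member too, fell by 4.30 ± 0.32. SOX10, the factor of migrating crest cells, differed by -0.33 ± 0.17 and did not pass (adjusted p = 0.166); it was singled out after its value was seen. Of 10 mesenchymal and fibroblast members, 5 rose, 3 fell and 2 did not pass, with 5 and 3 adjusted over the list alone (camera adjusted p = 0.167). LUM, the matrix proteoglycan lumican, rose by 4.70 ± 0.15 and FN1, fibronectin, by 1.72 ± 0.12, while THY1, a surface glycoprotein of stem cells and fibroblasts, fell by 1.42 ± 0.13.

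Mesoderm and endoderm markers fell or did not pass except for 1 member. Of 16 measured, 1 rose, 5 fell and 10 did not pass, the same as adjusted over the list alone (camera adjusted p = 0.167). CXCR4, a chemokine receptor that neural progenitors also carry, rose by 2.94 ± 0.20 (7.66-fold). KDR, a VEGF receptor, fell by 2.35 ± 0.14 (5.09-fold), and MIXL1, a primitive streak gene, by 0.83 ± 0.22 (adjusted p = 0.0179). MIXL1 lost its call without NPC replicate 2 (adjusted p = 0.0626) or NPC replicate 3 (adjusted p = 0.0535), and its adjusted p ran from 0.0101 to 0.113 over the settings tried. Of 12 surface ectoderm and trophoblast members, 2 rose, 2 fell and 8 did not pass, also when adjusted over the list alone (camera adjusted p = 0.965). The mean of that list was -0.058, its median was 0.014 and its test pointed up.

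EYA1, GATA2 and KRT7 are the members of the surface ectoderm and trophoblast list named by rule. EYA1, a transcriptional coactivator, rose by 0.42 ± 0.11 (adjusted p = 0.0166), GATA2 by 0.45 ± 0.14 (adjusted p = 0.0375), and the keratin KRT7 fell by 0.89 ± 0.30 (adjusted p = 0.0467). EYA1 lost its call without hESC replicate 1 (adjusted p = 0.0631) or NPC replicate 1 (0.0509). GATA2 lost its call without hESC replicate 1 (adjusted p = 0.111), NPC replicate 2 (0.110) or NPC replicate 3 (0.102). KRT7 lost it without any array but NPC replicate 1, with an adjusted p of up to 0.133. Over the settings tried, the adjusted p of EYA1 ran from 0.00464 to 0.0631, that of GATA2 from 0.0220 to 0.115 and that of KRT7 from 0.00799 to 0.195.

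Genes of epithelial junctions and their regulators fell. In the epithelial junction list 15 of 15 members fell, over all genes and adjusted over the list alone, with a mean of -3.30 (camera adjusted p = 2.45e-14, and adjusted p = 0.0102 with an estimated correlation). ESRP1 went from 9.72 ± 0.13 to 2.71 ± 0.092 (129-fold) and EPCAM from 9.47 ± 0.21 to 3.19 ± 0.12 (77.7-fold). The tight junction claudins CLDN6 and CLDN7 fell by 5.76 ± 0.27 and 3.99 ± 0.13, and GRHL2, a transcription factor of epithelial cells, by 3.92 ± 0.12. CLDN6, CLDN7 and GRHL2 were chosen after their values were seen.

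**Figure D3:**
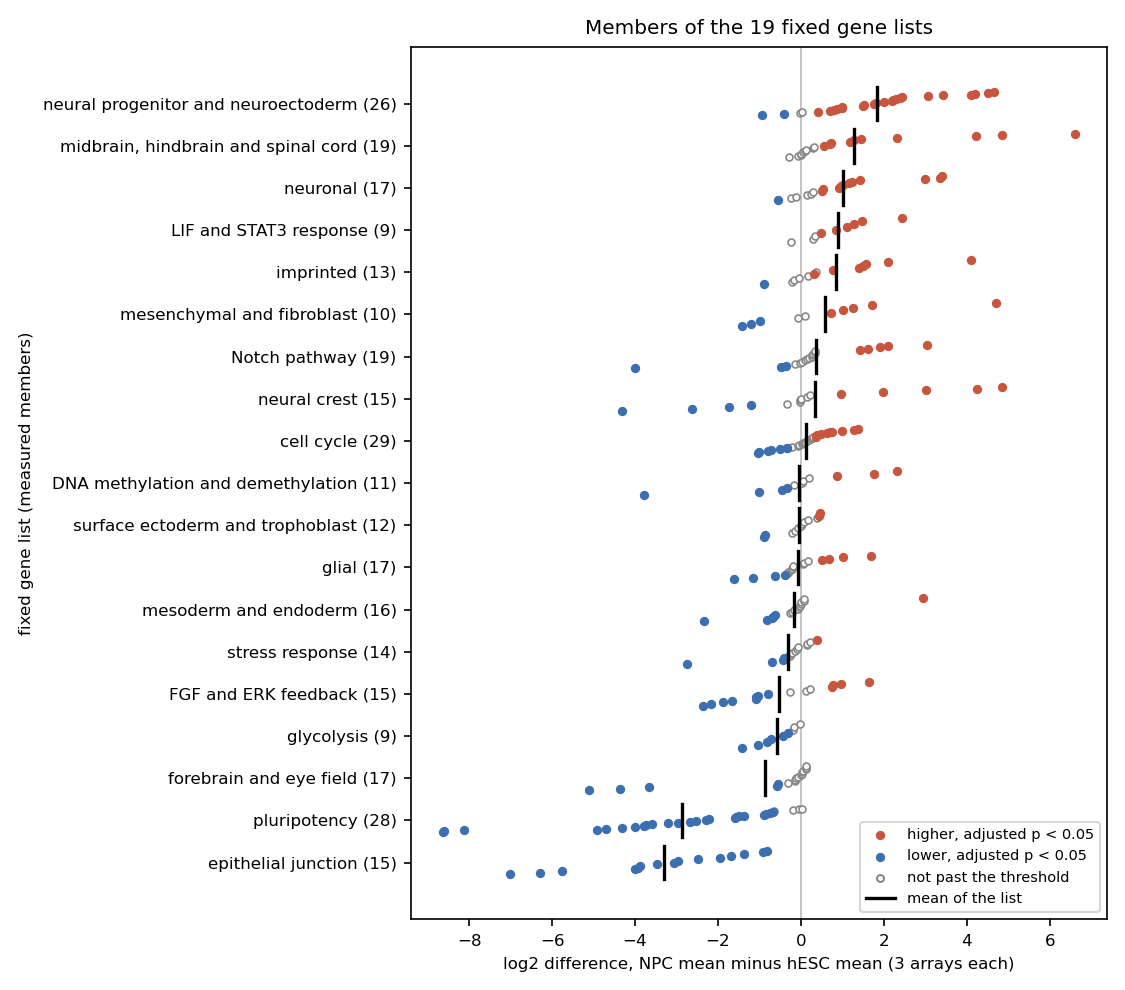
Log2 difference between NPC and hESC means (horizontal axis, 3 arrays per group) for each measured member of the 19 lists (vertical axis, number of members in brackets). Red and blue points are higher and lower in NPCs at an adjusted p under 0.05, open points did not pass, and the black bar is the mean of the list, which runs from -3.30 for epithelial junction to 1.83 for neural progenitor and neuroectoderm.

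Proliferation genes moved both ways. Of 29 measured cell cycle members, 10 rose, 7 fell and 12 did not pass (13 and 7 adjusted over the list alone), with a mean of 0.13 (camera adjusted p = 0.167). TYMS, thymidylate synthase, rose by 1.39 ± 0.097 (2.61-fold), and RB1, the retinoblastoma protein that restrains entry into S phase, rose by 1.27 ± 0.096 (2.42-fold). MCM5, a subunit of the replicative helicase, fell by 1.04 ± 0.14 (2.06-fold). MKI67, the antigen of cycling cells, rose from 8.32 to 9.32, a difference of 1.00 ± 0.096; it was singled out after its value was seen.

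Notch pathway genes moved both ways. Of 19 measured members, 5 rose, 3 fell and 11 did not pass, with 5 and 3 adjusted over the list alone. The ligand genes DLL1 and DLL3 rose by 3.04 ± 0.15 (8.20-fold) and 2.09 ± 0.12 (4.25-fold), while HEY2, a transcriptional repressor that Notch induces, fell 16.0-fold (SE 0.13 on the log2 scale). As a set the list did not pass in camera (mean 0.37, adjusted p = 0.0673). Over camera's alternatives with the preset correlation it ran from 0.0415 to 0.246, and it passed among these without hESC replicate 2 (adjusted p = 0.0415).

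FGF signalling genes moved both ways. In the FGF and ERK feedback list 4 of 15 measured members rose, 8 fell and 3 did not pass, the same as adjusted over the list alone. FGF2 itself, the growth factor that supports hESC self-renewal, fell by 2.37 ± 0.13 (5.18-fold), and its receptor gene FGFR4 by 2.18 ± 0.185 (4.53-fold). EGR1, an immediate early gene, rose by 1.64 ± 0.21 (3.11-fold). The set had a mean of -0.53 and did not pass in camera (adjusted p = 0.0673). Over camera's alternatives with the preset correlation it ran from 0.0399 to 0.108, and it passed among these without hESC replicate 2 (adjusted p = 0.0399) and with the mean of a gene's probe sets (adjusted p = 0.0483).

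In the LIF and STAT3 response list, 6 of 9 measured members rose, 0 fell and 3 did not pass, as adjusted over the list alone. LIFR, the LIF receptor, rose by 2.44 ± 0.12 (5.41-fold), and JUNB, an AP-1 subunit that STAT3 can induce, by 1.46 ± 0.20 (2.76-fold). The mean was 0.89 (camera adjusted p = 0.00151, but adjusted p = 0.113 with an estimated correlation). Per the labels LIF was part of the NPC medium.

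Genes of DNA methylation and demethylation moved both ways. Of 11 measured members, 3 rose, 4 fell and 4 did not pass, as adjusted over the list alone (camera adjusted p = 0.890). The de novo methyltransferases DNMT3B and DNMT3A fell by 3.79 ± 0.15 (13.8-fold) and 1.02 ± 0.096 (2.03-fold), and TET2, which oxidises methylcytosine, rose by 2.31 ± 0.14 (4.96-fold). The other called members, named after their values were seen, were TET1 and MBD4, lower by 0.46 and 0.33, and UHRF1 and MBD2, higher by 0.87 and 1.75. The list's mean was -0.053 with a test pointing down, and its median was 0.021.

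Imprinted genes, which are expressed from 1 parental copy, moved both ways. Of 13 measured, 7 rose, 1 fell and 5 did not pass (8 and 1 adjusted over the list alone). PLAGL1, a zinc finger factor that is also in the neural progenitor list, rose by 4.10 ± 0.10 (17.2-fold) and PEG10, a retrotransposon-derived gene, by 2.10 ± 0.105 (4.28-fold), while the noncoding RNA MEG3 fell by 0.88 ± 0.18 (1.85-fold, adjusted p = 0.00547, but 0.0575 in the unmoderated test). The mean was 0.84 (camera adjusted p = 0.00619, but adjusted p = 0.113 with an estimated correlation).

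Of 9 measured glycolysis members, 0 rose, 6 fell and 3 did not pass, as adjusted over the list alone. HK1, a hexokinase, fell by 1.41 ± 0.12 (2.67-fold), and GPI, glucose-6-phosphate isomerase, by 1.04 ± 0.10 (2.05-fold). The mean was -0.57 (camera adjusted p = 0.00198, but adjusted p = 0.129 with an estimated correlation). Oxygen was the same for both cell types per the labels.

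Of 14 stress response members, 1 rose, 4 fell and 9 did not pass, as adjusted over the list alone (camera adjusted p = 0.167). HMOX1, heme oxygenase, fell by 2.75 ± 0.15 (6.74-fold) and ATF3, a stress-induced transcription factor, by 0.71 ± 0.12 (1.64-fold). DDIT4, an inhibitor of mTOR signalling, rose by 0.40 ± 0.11 (adjusted p = 0.0198). DDIT4 lost its call without hESC replicate 1 (adjusted p = 0.0681), hESC replicate 2 (0.0627) or NPC replicate 1 (0.0630), with a range of 0.0123 to 0.0681 over the settings tried.

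Over the 19 lists together, camera called 9, of which 5 were higher and 4 lower in NPCs. With an estimated correlation 4 calls held, those of the pluripotency, neural progenitor and neuroectoderm, neuronal, and epithelial junction lists. The estimates for the forebrain and eye field and the imprinted lists, -0.0078 and -0.015, lay below the preset 0.01. Correlation among members therefore does not account for the loss of those calls. The estimates were 0.1, 0.044 and 0.11 for the midbrain, hindbrain and spinal cord, LIF and STAT3 response, and glycolysis lists. The camera adjusted p of the pluripotency list went from 1.43e-17 to 0.0102 at an estimate of -0.032, so this setting is stricter even then. A call lost under it is therefore not in itself evidence of correlated members. For the lists with positive estimates, correlation and the stricter setting cannot be told apart. The lists overlap in single genes such as PAX3, PLAGL1, DNMT3B and FOXD3, so their tests are not independent.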

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

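Probe sets with no gene name here entered no comparison of named genes, yet many of them differed between the cell types, and that is why they are listed. Of 37519 such probe sets, 1133 were at least 2-fold higher and 1085 at least 2-fold lower in NPCs at an adjusted p under 0.05 in limma over all 53617 probe sets. Without the 2-fold condition, 2554 were higher and 2415 lower, which is 13.2% of the unnamed probe sets against 26.8% of the named ones. The unnamed probe sets were dimmer, with a median level of 3.05 against 4.68. The largest falls were in probe sets 17124618 (from 10.7 to 2.10, a difference of -8.58 ± 0.14, SE) and 17112555 (from 10.5 to 2.71, a difference of -7.82 ± 0.18). The largest rises were in 17122270 (from 2.83 to 9.18, a difference of 6.34 ± 0.21) and 17079968 (from 3.74 to 9.83, a difference of 6.10 ± 0.21). No explanation was tested for these probe sets. Groups of 3 arrays are too small for the test of single outlying arrays, so none was run.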

How the results depend on the processing

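The gene counts stayed within 1.5 times their value in every setting but the following. Over all 53617 probe sets, 4776 were higher and 4514 lower, and 2038 and 1910 of them at least 2-fold, since more features were tested. Without genes below the 50th percentile of level, 520 genes were at least 2-fold lower, because fewer were tested. Under limma treat, 401 and 363 passed for the 2-fold difference. The 9 list calls became 4 with an estimated correlation, 16 with fry and 19 with fry's mixed test; fry does not compare a list with other genes. Leaving out 1 array gave 2301 to 2393 genes higher, 2176 to 2291 lower and 8 to 11 lists. Over all genes, 4345 to 4465 of the 5249 calls were kept in the same direction without 1 array. Among the 68 named genes 63 kept their call without each array, and over all settings 1114 results for named genes held their call and 23 lost it. Most named genes were picked for a call or a large difference, so they are steadier than called genes in general. For the lists 332 results held, 8 lost and 20 gained a call, and no direction of a called list or gene turned. The adjusted p of the forebrain and eye field list ran from 2.33e-06 to 0.129, of the midbrain, hindbrain and spinal cord list from 1.39e-05 to 0.129, of LIF and STAT3 response from 5.54e-06 to 0.113, of imprinted genes from 8.45e-07 to 0.113, of glycolysis from 3.69e-05 to 0.129 and of neuronal genes from 4.90e-07 to 0.0715. Other scalings moved the median of all genes from -0.019 to -0.017 and -0.026.

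Same-numbered hESC and NPC arrays deviated from their group means with correlations of 0.020, 0.011 and 0.011 across genes, so the shared number is not taken to pair them. All 6 arrays correlated best with their own number, which is only a hint from the data. With the replicate block, 2575 genes were higher and 2415 lower, against 2662 and 2587, and no list or named gene changed its call. Signal over background limits the dim genes, for which the table gives no detection call.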

Other observations

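The gene families in the first paragraphs were chosen after their values were seen, so their p-values, adjusted over the 9 families, take no account of that choice; the tests of possible sources below were also chosen after seeing the result. The microRNA cluster of pluripotent cells fell with the other pluripotency genes. MIR302A, MIR302B, MIR302C, MIR302D and MIR367 fell by 7.08, 5.04, 6.95, 4.25 and 5.50 (5 of 5 called, camera p = 2.43e-08, 2.19e-07 adjusted over the 9 families, adjusted p = 0.063 with an estimated correlation). Whether mature or precursor RNA gave this signal was not tested. Of 9 metallothionein genes, with the pseudogene MT1L among them, 6 fell (MT1L too) and 3 did not pass (camera adjusted p = 1.97e-06, and 0.114 with an estimated correlation). MT1X and MT1F fell by 1.96 ± 0.15 and 2.49 ± 0.18, against 8.56 for MT1H, while MT2A differed by -0.29 ± 0.10 and did not pass (adjusted p = 0.060). All 8 SNAR small noncoding RNA genes fell, with a median of -2.57 (camera adjusted p = 1.91e-06, and 0.122 with an estimated correlation; 9.90e-05 adjusted over 233 families of genes sharing the start of their symbol). Members of the metallothionein and SNAR families are near-identical and can share probes.

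Genes of axon guidance and Wnt reception moved both ways. Of 21 Eph receptors and ephrins, 10 rose, 4 fell and 7 did not pass (camera adjusted p = 0.000986, and 0.122 with an estimated correlation). EPHA3 rose by 3.94 ± 0.13, EPHA4 by 3.42 ± 0.098 and EFNB2 by 2.92 ± 0.10, while EPHA1 fell by 2.84 ± 0.22. Of 21 slit, plexin, netrin and netrin receptor genes, 11 rose, 2 fell and 8 did not pass (camera adjusted p = 0.00782, and 0.155 with an estimated correlation). Of these 21, 2 lost their call on a second quantile normalization and 1 on centring. SLIT2, PLXNA2 and UNC5C rose by 3.13 ± 0.14, 3.26 ± 0.16 and 2.76 ± 0.11, and the netrin receptors UNC5B and UNC5D fell by 2.96 ± 0.15 and 3.34 ± 0.22. Of 10 frizzled receptor genes, 6 rose, 3 fell and 1 did not pass (camera adjusted p = 0.080, and 0.155 with an estimated correlation), with FZD10 higher by 2.35 ± 0.11 and FZD7 lower by 1.76 ± 0.096. Of 27 HOX cluster genes measured, 3 rose (HOXA2, HOXB2 and, by 0.57 ± 0.19, HOXB1), HOXC12 fell by 0.34 ± 0.10, and 23 did not pass; as a set they did not pass (camera adjusted p = 0.477), and 1 called gene lost its call under each other scaling. Of 38 genes whose symbols start with CEP, most of them of the centrosome, 16 rose, 4 fell and 18 did not pass (camera adjusted p = 0.000556, and 0.122 with an estimated correlation; 0.0144 adjusted over the 233 families). The 38 include the pseudogenes CEP170P1 and CEP192P1, which did not pass, and the noncoding CEP83-DT, which rose by 0.82.

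Of 17 genes whose symbols start with IFT, for intraflagellar transport along cilia, 10 rose, 0 fell and 7 did not pass, the pseudogene IFT122P3 among the 7. In the screen of 233 families 5 passed: those starting with SNAR, IFT, MT (adjusted p = 0.00355, 11 genes), PCDHB (adjusted p = 0.0109, 9 of 19 higher and 0 lower, near-identical protocadherin copies) and CEP. With an estimated correlation the unadjusted camera p was 0.0154 for PCDHB and 0.0426 for the 11 MT genes. The IFT genes had a median of 0.501 (IFT172 and IFT27 at -0.017 and -0.015; camera adjusted p = 0.00212; unadjusted p = 0.014 with an estimated correlation, or 0.063 adjusted over the 9 families), with IFT81 and IFT88 up by 1.70 ± 0.10 and 1.20 ± 0.15. Equally bright genes did not share the rise, since random lists matched on level had medians centred on 0.00621. The IFT median was 0.501 ± 0.093 (bootstrap SE over the genes), and these genes were picked for their shift. Quantile normalization holds the centre of such random lists near 0, so no conclusion about a normalization trend is drawn. Multiciliated cells stay open: the median of 12 measured markers was 0.0275 ± 0.10 (bootstrap SE), but 7 of them lie below the 25th percentile of level. Among the markers MYB rose by 0.81, RSPH1 fell by 0.47 and FOXJ1 did not pass. Fewer cycling cells stay open too, because the median of 11 G2 and mitosis genes was 0.256 ± 0.15 (bootstrap SE), with 5 higher and 1 lower. A larger share of cells with a primary cilium may be the source, a hypothesis that RNA levels alone do not test.

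Pluripotency genes kept different shares of their hESC level. ESRG, L1TD1 and ZFP42 kept at most 0.292%, 0.358% and 0.428% by their upper 95% bounds, and less if their NPC values are background. Of the other 21 list members that fell, 5 were dim in NPCs (below the 25th percentile of level), which leaves their shares open, and 16 kept 3.31% to 62.2%, with lower bounds from 2.61%. Among those 16, PRDM14, DPPA5, NODAL and LEFTY2 lay at 3.32, 3.37, 3.62 and 3.67 in NPCs, close to the 25th percentile of 3.25. What these kept may be background. ESRG, L1TD1 and ZFP42 have the lowest shares of the list and were set as the bound after the values were seen. Undifferentiated hESCs left among the NPCs would bring every hESC transcript in 1 proportion, and so at most the lowest share. They are argued against as the main source for members well above that percentile in NPCs, such as LIN28B, DPPA4 and SALL4 at 8.80, 8.38 and 7.98. Expression by the NPCs themselves may remain, as a hypothesis, while background signal and probe-specific compression stay open.

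PAX3, TFAP2B, SOX5, SNAI2 and TWIST1, all transcription factors, are the 5 crest list members that rose, and were picked for that, with a median of 3.01. FOXD3, ETS1 and SNAI1, transcription factors of the same list, fell by 4.30, 1.73 and 1.20, and the list as a set did not pass (camera adjusted p = 0.441). Migratory or differentiating crest cells among the NPCs stay open. The 8 measured markers of them had a median of -0.00586 ± 0.14 (bootstrap SE), with 0 higher and ERBB3 lower by 2.62 ± 0.13, but 7 of the 8 are in the crest list and were already known not to rise. A dorsal identity of the neural cells may be the source. Over 9 dorsal and 9 ventral neural tube genes the medians differed by 1.13 (exact permutation p = 0.00504, one-sided), but over the 5 and 5 genes outside the fixed lists, a condition added after the first value was seen, the difference was -0.319 (exact permutation p = 0.643, one-sided). Of the dorsal genes outside the lists BMP5 and ZIC4 rose by 3.18 and 1.04, ZIC5 fell by 1.12, and GDF7 and OLIG3 did not pass, so this hypothesis stays open.

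The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For genes, 1 of 10 splits reached the real count of 5249, and the highest other split gave 0. For the lists, 1 of 10 reached the real count of 9, and the highest other gave 6. Every other split mixes hESC and NPC arrays on each side. The difference between the cell types then adds to the spread within each side, and part of it remains between the sides. The 0 and the 6 are therefore not chance levels, and no conclusion is drawn from them. No shift of a whole chromosome was called: camera called 0 of 23 chromosomes (1 to 22 and X), with 0 at an unadjusted p under 0.05. The lowest p was 0.212, and medians ran from -0.075 to 0.030. Without each array in turn the count was also 0. A change shared by both cell types would cancel in this comparison, and dim genes can hide a shift. A gained or lost chromosome is therefore not ruled out.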
